A study of Homo sapiens with 9 samples.

How the data were processed

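RNA was measured by sequencing in H295R cells, a human line derived from an adrenocortical carcinoma that makes steroid hormones. The 9 libraries fell into 3 groups of 3 by their sample titles and genotype labels: wild type (WT), SGPL1 knockout (KO) and SGPL1 overexpression (OE). The series' design text calls the libraries of a group biological replicates. The labels describe total RNA extracted with an RNeasy kit, poly-A selection and random priming, and no treatment. Whether the replicates came from separate cultures or clones is not given, so p-values measure the spread between these libraries, part of which may be technical. The strand protocol, the site and kind of edit in the KO cells and the construct used for overexpression are not given in the sources used here.

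The authors deposited whole-number read counts per gene, not normalized, 1 column per library. Per the file headers, the counts were made with featureCounts 1.5.2 on an Ensembl release 101 annotation of the GRCh38 assembly, with only the annotation and output options on the command line. With those options featureCounts counts reads rather than fragments, ignores strand and leaves out reads that map to several places or overlap more than 1 gene. Per the submitters' processing notes, FastQC, HISAT2 1.03, Subread, featureCounts 0.1.0 and DESeq2 were used, so the notes and the header give different featureCounts versions. Because strand was ignored, reads from a stretch shared by a gene and an antisense gene cannot be told apart and were left out. Genes that overlap others may thus have partial counts. Because multiply mapped reads were left out, genes with a close copy (CYP21A2, HSD3B2, CYP11B1, SERF1B, ribosomal protein genes, histone genes and mitochondrially encoded genes among those named here) are uncertain in level.

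The files list 60671 genes, and 0 lines lack a gene identifier. Symbols were found for 58502 identifiers (96.4%) and a biotype for 58453 (96.3%, from GENCODE release 29). A total of 32845 genes had no count in any library. Library totals were 8549071, 8006873 and 8185527 counts for WT replicates 1 to 3, 8553964, 9220402 and 9351139 for KO, and 9194831, 8020836 and 10895080 for OE. At these depths and with 3 libraries per group, the median standard error of a log2 fold change was 0.187. No 2 libraries of the same group agreed within sampling noise by a chi-square comparison of their counts, so each was kept as 1 replicate.

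From the counts, expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr with a minimum count of 10, and all 9 libraries in one fit with a term for the group. The filter left 14150 genes, 12258 of them protein-coding. The common biological coefficient of variation was 0.15, on 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene comes from this edgeR test unless another tool is named. Group levels are means of CPM (counts relative to the TMM-scaled library total) with the SD over 3 libraries, and fold changes are log2 with their standard error.

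A total of 39 gene lists were fixed before the data were examined, together with the design, the alternatives and the rule for named genes. The 35 lists with at least 5 genes tested were compared with the other genes by camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and adjustment over the 35 lists. The adjusted p of a list is from camera. The same test with a correlation estimated per list was run beside it, as was fry. Members passing the gene test are counted over all genes tested, and again "adjusted over the list alone". Lists of fibroblast, epithelial, leukocyte and endothelial markers had 4, 4, 1 and 0 genes tested and were not tested as lists. The highest count of any of their genes in any library was 372, 293, 26 and 15. The histone list holds replication-dependent histone genes, whose mRNAs mostly lack a poly-A tail. In these poly-A selected libraries their counts may be a residue, so changes of that list are uncertain.

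The text names SGPL1, the 10 genes with the largest rise and the 10 with the largest fall per comparison, up to 4 members of each list with the smallest adjusted p, and the 10 genes called in opposite directions in KO and OE with the largest smaller change. The largest changes were taken among protein-coding genes with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the groups. Up to 8 members were allowed for the sphingolipid, S1P, steroidogenesis, cholesterol biosynthesis and respiratory chain lists. Some genes that this rule takes are not reported here. Where a group had no count, the fold is a lower bound against 3 counts per library. With 1 to 3 counts the ratio is given with its 95% counting interval. Such floors and intervals cover counting error only.

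The KO and OE comparisons share the WT libraries, so overlaps of their calls were set beside 20 simulations of unchanged groups against the same WT libraries and beside the overlap of independent lists. The simulated groups were drawn around the mean of these WT libraries. The pipeline was tested on simulated counts in which known genes were changed. On 13870 genes it called 21.5%, 63.6% and 92.3% of the genes changed 1.5, 2 and 4-fold for KO against WT, 31.8%, 77.3% and 96.9% for OE against WT, and 30.8%, 76.2% and 95.4% for OE against KO. It called 7, 11 and 19 unchanged genes in these comparisons. The simulated genes were drawn independently and without a trend on transcript length. The real libraries had slopes on log2 transcript length from -0.26 (OE-labelled replicate 2) to 0.156 (KO replicate 3). These shares and false calls therefore do not give the rates in the real data.

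The alternatives were RLE and upper-quartile scaling, library totals alone, no filter on low counts, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the 2 groups compared in the fit, the replicate number as a block, an adjusted p under 0.01, each library left out in turn, and the other list tests. The filter of 1 CPM in 3 libraries was planned as a stricter one but kept 14381 genes. Added after the results were seen were a correction of each library for its trend of counts on transcript length, leaving out WT replicate 2 and OE replicate 2 together, and leaving out genes in chromosome blocks. Transcript lengths, each of a single annotated transcript per gene, came from GENCODE release 29 and were known for 99.4% of the genes tested. A block joins the overlapping windows of 51 neighbouring tested genes whose median log2 fold change, KO against WT, was over 0.4 in either direction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.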

Results

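The expression of polyadenylated RNA was compared between H295R adrenocortical carcinoma cells without a stated change (WT), cells labelled as SGPL1 knockout (KO) and cells labelled as overexpressing SGPL1 (OE), with 3 libraries each. SGPL1 encodes sphingosine-1-phosphate lyase, which cleaves sphingosine-1-phosphate (S1P) irreversibly into phosphoethanolamine and a fatty aldehyde. The series' title asks what elevated SGPL1 does to metabolic rate in adrenocortical carcinoma. Library totals ran from 8006873 to 10895080 counts, and between 18634 and 19769 genes had at least 1 count. The first principal component of log2 CPM held 49% of the variance and placed the KO libraries at 47.7 to 59.6, the WT libraries at -24.6 to -4.9 and the libraries labelled OE at -54.1 to -31. Transcripts of ribosomal proteins made up 5.56%, 6.73% and 5.12% of counts in the WT libraries, 4.85%, 4.53% and 4.07% in KO, and 7.23%, 9.26% and 7.23% in the libraries labelled OE. In the latter, short transcripts also had higher and long transcripts lower counts than in WT. For each library, log2 CPM was taken relative to the mean of the 3 groups for each gene. Its slope on log2 transcript length was 0.07, -0.072 and 0.131 in WT, 0.049, 0.109 and 0.156 in KO, and -0.086, -0.26 and -0.097 in the libraries labelled OE. The signs of these slopes are relative to that mean.

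SGPL1 (ENSG00000166224, chromosome 10, 70815948 to 70881184, GRCh38) had lower counts in KO than in WT, and its counts were not higher in the libraries labelled OE. Its level was 94.3 ± 9.6 CPM in WT, 48.3 ± 5.1 CPM in KO and 93.5 ± 10.7 CPM in the libraries labelled OE (SD, n = 3). The KO level was 51.2% of WT, a log2 fold change of -0.97 ± 0.14 (edgeR adjusted p = 0.000105), with no overlap of the groups. By library, WT had 101.5, 83.4 and 98.1 CPM, KO 47.2, 43.9 and 53.8 CPM, and the libraries labelled OE 98.1, 81.3 and 101.2 CPM, from 404 counts at the lowest to 1076 at the highest. For OE against WT the log2 fold change was -0.01 ± 0.14 (adjusted p = 0.966, 95% interval -0.34 to 0.32). With the counts corrected for transcript length it was 0.23 ± 0.11 (adjusted p = 0.129). The counts cover the gene as a whole, so reads of a transcript disrupted by an edit are still counted, and a coding sequence added on a vector adds counts only if its reads map to the gene. Directions between the libraries labelled OE and the other groups are therefore given by label, with SGPL1 counts not higher in them than in WT.

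**Figure D1:**
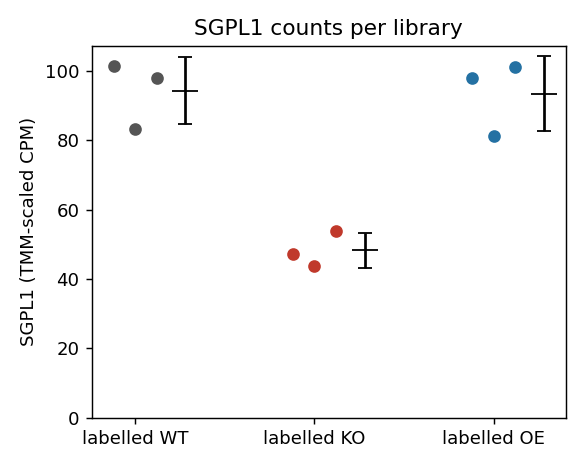
SGPL1 level per library, in TMM-scaled CPM, for the WT, KO and OE labels. Dots are libraries and the bars give the mean and SD of 3. KO lies at 43.9 to 53.8 CPM, below every WT library, and the libraries labelled OE lie at 81.3 to 101.2 CPM, beside 83.4 to 101.5 CPM in WT.

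The comparison of KO with WT asks what differs when SGPL1 is disrupted. Several genes that were close to silent in one of these groups were well expressed in the other. CILP2 (ENSG00000160161, chromosome 19, 19538248 to 19546659), a cartilage matrix protein, rose from 0.3 to 66.8 ± 8.35 CPM, a log2 fold change of 7.69 ± 0.33 (adjusted p = 1.58e-10). The potassium channel gene KCNT2 (ENSG00000162687, chromosome 1, 196225779 to 196609225) had no count in WT and was at least 31.4-fold higher in KO, and TDO2, which breaks down tryptophan, was at least 19-fold higher. UTS2 and DMTN had 1 to 3 counts over the WT libraries, with ratios of 116 (95% counting interval 31.9 to 967) and 102 (27.8 to 846). EGLN3, a prolyl hydroxylase of the hypoxia response, rose by 6.33 ± 0.50 on the log2 scale, the complement gene C7 by 5.61 ± 0.43, PCDH17 by 5.06 and NAXD by 4.92 ± 0.32. RAB31 (ENSG00000168461, chromosome 18, 9708275 to 9862551), a regulator of vesicle traffic, was at 24.0 ± 6.42 CPM in WT, had no count in KO and was at least 72.3-fold lower. MARVELD2 was at least 25.6-fold and SH3TC1 at least 23.5-fold lower. CYP27A1 (ENSG00000135929, chromosome 2, 218781749 to 218815293), which hydroxylates cholesterol at its side chain, was higher in WT with a ratio of 362 (99.8 to 2990), TPD52 with 177 (31.4 to 7050) and CD109 with 140 (38.4 to 1160). DSG2 changed by -6.13 ± 0.44, BRSK2 by -5.63, CADPS by -5.40 ± 0.36 and TSHR, the receptor of thyrotropin, by -5.24 ± 0.65. In all, 1296 genes were higher and 1359 lower in KO, 18.8% of those tested, with 1046 at least 2-fold changed. The groups did not overlap in 4979 genes (35.2%, where chance gives 10%). Without KO replicate 2 the number of lower genes was 885. KCNT2, C7, TDO2 and MARVELD2 lie in chromosome blocks whose genes shifted together, described further on.

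Genes of cholesterol synthesis were higher in KO than in WT. Of 25 tested, 19 rose and 2 fell (19 and 2 adjusted over the list alone), with a median log2 fold change of 0.60. HMGCS1, an early enzyme of the pathway, rose from 352 to 659 CPM (log2 fold change 0.90 ± 0.13, adjusted p = 0.000124). DHCR7 rose by 0.79 ± 0.10, MSMO1 by 0.83 ± 0.11, IDI1 by 0.82, HSD17B7 by 1.18 ± 0.14 and TM7SF2 by 3.12 ± 0.45. SQLE (chromosome 8, 124998497 to 125022283), the epoxidase that acts on squalene, went the other way, from 102.2 ± 10.2 to 38.3 ± 1.43 CPM (-1.42 ± 0.14, adjusted p = 3.65e-06), as did PMVK, chosen after its values were seen (-0.70 ± 0.20, adjusted p = 0.0212). The list differed from the other genes in camera (adjusted p = 1.82e-07, and adjusted p = 0.0398 with an estimated correlation). It is the only one of the 7 lists called for KO against WT that was also called with an estimated correlation. Without KO replicate 2 the number of lists called was 4, and without WT replicate 2 it was 11. HMGCS1, MSMO1 and HSD17B7 lie in the chromosome blocks. With all block genes left out, 15 of 19 members rose and 2 fell, with a median of 0.59 (adjusted p = 5.91e-06, and adjusted p = 0.128 with an estimated correlation). SOAT1 (ENSG00000057252, chromosome 1, 179293714 to 179358680), which esterifies cholesterol for storage, rose from 338.1 ± 16.1 to 1194.4 ± 133 CPM (1.82 ± 0.11, adjusted p = 1.72e-08) and lies in a block on chromosome 1 with a median shift of 0.51. APOE rose by 3.05 ± 0.34, and the exporter ABCG1, in a block on chromosome 21, changed by -3.29 ± 0.45. The list of cholesterol efflux and storage held 4 rises and 1 fall among 16 genes (median 0.07, adjusted p = 0.384).

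Steroidogenic genes were higher in KO as well. Of 20 tested, 7 rose and none fell (8 and 0 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.00279, and adjusted p = 0.33 with an estimated correlation). STAR, which carries cholesterol into mitochondria, rose from 318 ± 19.7 to 543.1 ± 56.9 CPM (0.77 ± 0.11, adjusted p = 8e-05). SULT2A1, which sulfates dehydroepiandrosterone, rose from 178.8 ± 15 to 359.3 ± 14.5 CPM (1.01 ± 0.11, adjusted p = 6.09e-06). The lipoprotein receptor SCARB1 rose by 0.73 ± 0.11 and HSD3B2 by 0.88 ± 0.15. CYP11B1, the 11-beta-hydroxylase, had 1 to 3 counts over the WT libraries and a ratio of 23.7 (6.22 to 201), and its reads can be confused with those of its close copy. Among regulators and markers of the adrenal cortex, 8 of 25 rose and 1 fell (median 0.21, adjusted p = 0.0647), among them DLK1 from 2595 to 5796 CPM (1.16 ± 0.11, adjusted p = 1.78e-06) and NR0B1 by 1.68 ± 0.24.

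Glycolysis and fatty acid synthesis followed the same direction. Of 23 glycolytic genes, 13 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 0.48 (adjusted p = 0.000365, and adjusted p = 0.415 with an estimated correlation). HK2, a hexokinase, rose from 8.65 ± 0.928 to 26.2 ± 2.23 CPM (1.59 ± 0.19, adjusted p = 1.51e-05). ALDOC rose by 0.87 ± 0.15, LDHA by 0.62 ± 0.11 and PKM by 0.63 ± 0.12. The phosphofructokinase PFKL, chosen after its values were seen and in a block on chromosome 21, changed by -0.71. Outside the chromosome blocks 9 of 18 rose and 0 fell, with a median of 0.42. In fatty acid synthesis 6 of 15 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.31 (adjusted p = 0.0113, and adjusted p = 0.33 with an estimated correlation). The desaturases FADS2 and FADS1 rose by 0.65 ± 0.11 and 0.56, and ACSS2, which makes acetyl-CoA, by 0.60. SREBF1, a transcription factor that switches such genes on, fell from 70.1 to 20.3 CPM (-1.79 ± 0.19, adjusted p = 6.03e-06). The fatty acid call was lost without KO replicate 2 (adjusted p = 0.0556) and without KO replicate 3 (adjusted p = 0.0707).

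Ribosomal protein genes were lower in KO. Of 49, 10 fell and none rose (12 and 0 adjusted over the list alone), with a median of -0.30 (adjusted p = 7.39e-05, and adjusted p = 0.765 with an estimated correlation), and fry did not call it (adjusted p = 0.2). RPL12 went from 543.4 to 348.1 CPM (-0.64 ± 0.13, adjusted p = 0.0018). These are short transcripts, and after the length correction the ribosomal median was -0.20 with 18 lower (camera adjusted p = 0.000533, and adjusted p = 0.644 with an estimated correlation). The unfolded protein response held 7 falls and 1 rise among 20 genes (7 and 1 adjusted over the list alone), with a median of -0.27 (adjusted p = 0.0464, and adjusted p = 0.33 with an estimated correlation). The chaperones CANX and HSPA5 changed by -0.89 ± 0.10 and -0.54 ± 0.10, while ATF6, a sensor of this response, rose by 0.58 ± 0.11. CANX and ATF6 lie in chromosome blocks. Of the 13 mRNAs encoded in mitochondria 1 passed the gene test, MT-ND4 at 0.50 ± 0.14 (adjusted p = 0.0188), and the list had a median of 0.25 (adjusted p = 0.0464, and adjusted p = 0.649 with an estimated correlation). MT-ND4 was not called without WT replicate 2 (adjusted p = 0.0799), KO replicate 2 (0.124) or KO replicate 3 (0.0568). The mitochondrial list lost its call without WT replicate 2 (0.104), KO replicate 2 (0.165) or KO replicate 3 (0.0517), and also with upper-quartile scaling (0.0529), library totals alone (0.0578), fry (0.083), and WT replicate 2 and OE-labelled replicate 2 left out together (0.0858). The unfolded protein response lost it without WT replicate 2 (0.0622) or 3 (0.0579), KO replicate 1 (0.102), 2 (0.107) or 3 (0.0517), and without the OE-labelled replicates 1 (0.0522) or 3 (0.0564).

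Genes that make and break down sphingolipids, the substrates upstream of SGPL1, did not move as a group in KO. Of 38 tested, 6 rose and 3 fell, with a median of 0.07 (camera adjusted p = 0.431). UGT8, which makes galactosylceramide, went from 0.16 to 2.84 CPM (4.07 ± 0.92, adjusted p = 0.0048). The ceramide synthase CERS6 rose by 0.76 ± 0.21 (adjusted p = 0.0198) and ORMDL3, an inhibitor of the first step of the pathway, changed by -0.44 ± 0.13 (adjusted p = 0.028). CERS6 was not called without WT replicate 1 (adjusted p = 0.0879), WT replicate 2 (0.0875) or KO replicate 3 (0.103), and ORMDL3 not without WT replicate 1 (0.13) or KO replicate 1 (0.0797), 2 (0.0829) or 3 (0.0762). None of 7 receptors and transporters of S1P passed the test (median -0.17, adjusted p = 0.667). Genes of phosphatidylethanolamine synthesis had 5 rises and no fall among 9, with a median of 0.38 and an adjusted p of 0.0647 for the list. SELENOI rose by 0.64 ± 0.14, PCYT2 by 0.58 ± 0.14 and ETNK1 by 0.52 ± 0.12. That list passed without WT replicate 2 (0.045) or OE-labelled replicate 2 (0.0494).

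Part of the difference between KO and WT followed position on the chromosomes. In 13 blocks of neighbouring genes the median over 51 genes was shifted by more than 0.4, and these blocks held 1233 genes (8.7% of those tested) and 556 of the called genes (20.9%). On chromosome 5 from 149494314 to 181272307, 131 of 153 genes were lower in KO, 98 of them called, with a median of -0.87. The medians there were -0.82, -0.88 and -0.81 in the 3 KO libraries and -0.01 for OE against WT. A block on chromosome 20 from 270863 to 31801805 had a median of -0.66 over 130 genes, with 113 lower. On chromosome 1 from 160894980 to 201884291 the median was 0.51 over 147 genes, and on chromosome 5 from 218241 to 44808777 it was 0.44 over 120 genes. Outside the blocks 1045 genes were higher and 1054 lower. All 7 lists called for KO against WT were also called with the block genes left out. None of them was then called with an estimated correlation (camera adjusted p = 0.128 to 0.637). Of the genes named here, ATF6, HSD17B7, SOAT1 and KCNT2 lie in the chromosome 1 block, C7, HMGCS1, MARVELD2, SERF1B and CANX in blocks on chromosome 5, TDO2 and MSMO1 on chromosome 4, CHGB and ISM1 on chromosome 20 and ABCG1 and PFKL on chromosome 21. SGPL1, on chromosome 10, lies in none.

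**Figure D2:**
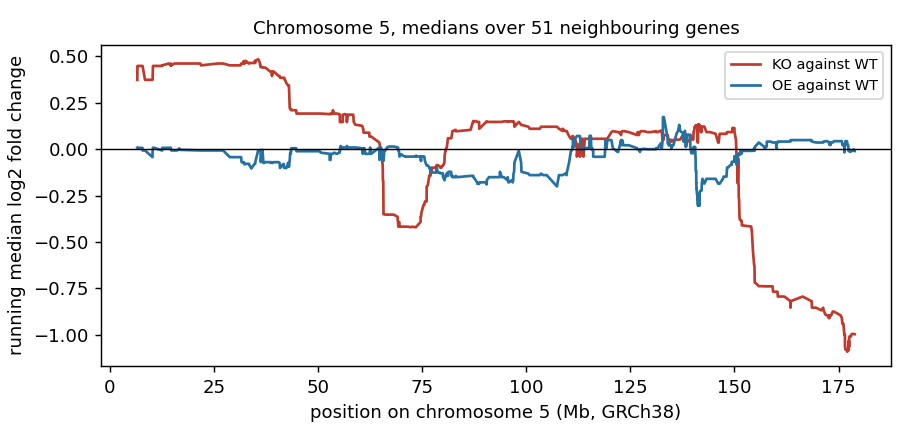
Running median of log2 fold changes over 51 neighbouring genes along chromosome 5, against position in megabases, for KO against WT and for OE against WT. The KO line lies above 0 on the short arm, where the block median is 0.44, and below 0 near the end of the long arm, where it is -0.87, while the OE line lies between -0.30 and 0.17.

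The libraries labelled OE were set beside WT to ask what differs with added SGPL1, although the counts of the SGPL1 gene were not higher in them. The largest rise among the named genes was that of HSD3B2, and CYP21A2 rose as well. HSD3B2 (ENSG00000203859, chromosome 1, 119414931 to 119423035), which turns pregnenolone into progesterone, went from 13.8 ± 0.8 to 102.8 ± 5.96 CPM (2.90 ± 0.15, adjusted p = 9.02e-09). CYP21A2 (ENSG00000231852, chromosome 6, 32038327 to 32041644), the 21-hydroxylase, went from 102.1 ± 8.28 to 322.1 ± 27 CPM (1.66 ± 0.13, adjusted p = 2.06e-06). Both have close copies in the genome, so their levels are uncertain. LAPTM4B, a lysosomal membrane protein, rose by 1.82 ± 0.10, FAM166B by 2.10 ± 0.20, MAP3K7CL by 1.81, the receptor TNFRSF12A by 1.80 ± 0.18, FITM1 by 1.77, the protease inhibitor SERPINE2 by 1.73, the carbonic anhydrase CA2 by 1.68 ± 0.19 and VPREB3 by 1.65. FN1 (ENSG00000115414, chromosome 2, 215360440 to 215436073), which encodes fibronectin, went from 9.51 ± 3.82 to 1.14 CPM (-3.07 ± 0.44, adjusted p = 0.000381). The proliferation marker MKI67 (chromosome 10, 128096659 to 128126423) went from 210.2 ± 106 to 33.8 ± 10.2 CPM (-2.63 ± 0.31, adjusted p = 0.000104). COL5A2 changed by -2.74 ± 0.46, CRACD by -2.65, GOLGB1 by -2.45 ± 0.30, CENPF by -2.43 ± 0.27, GLI2 by -2.38 and HSPG2 by -2.35. SERF1B changed by -2.95 ± 0.80 (adjusted p = 0.0167), but by -0.68 without WT replicate 2 (adjusted p = 0.432), and limma-voom did not call it (adjusted p = 0.172).

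In all, 1365 genes were higher and 1559 lower in the libraries labelled OE than in WT, 20.7% of those tested, with 664 at least 2-fold changed. With library totals alone as scaling, the median of all genes was -0.129 and the share of higher genes among the calls was 25.9% rather than 46.7%. The groups did not overlap in 5149 genes (36.4%, where chance gives 10%). Without WT replicate 1 the counts were 557 and 824, without WT replicate 3 they were 485 and 759, and without OE-labelled replicate 2 they were 817 and 1032. The number at least 2-fold changed was 385 without WT replicate 3. Transcript length moved with this comparison. Over 5 groups of genes ordered by length, from the shortest (median 1103 nt) to the longest (6981 nt), the median log2 fold change went from 0.294 through 0.124, 0.002 and -0.123 to -0.334, with 610 higher and 50 lower genes in the first and 70 higher and 783 lower in the last. Among the genes with the largest falls MKI67 has 12678 nt, CENPF 10307 nt, GOLGB1 11187 nt and FN1 7898 nt, but SERF1B has 703 nt. After correction for length MKI67 was at -2.05 (adjusted p = 1.02e-06), CENPF at -1.92, GOLGB1 at -1.91, FN1 at -2.68, SERF1B at -3.12, HSD3B2 at 2.74, CYP21A2 at 1.54 and LAPTM4B at 1.54.

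**Figure D3:**
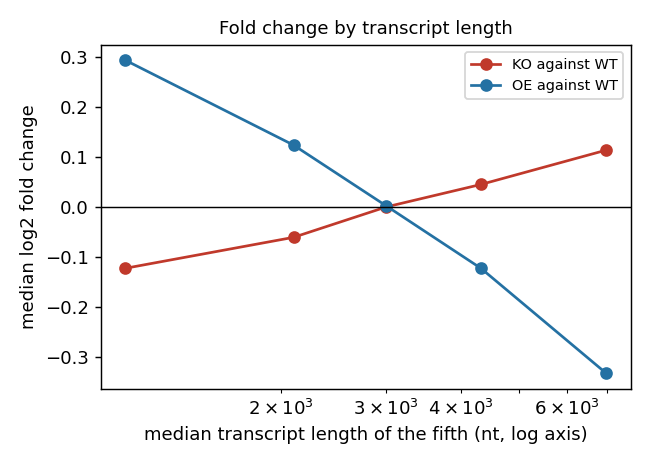
Median log2 fold change in 5 groups of genes ordered by transcript length, on a log axis in nucleotides, for KO against WT and OE against WT. For OE against WT the median goes from 0.294 in the shortest genes to -0.334 in the longest, and for KO against WT from -0.123 to 0.114.

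Genes of the ribosome and of oxidative phosphorylation were higher in the libraries labelled OE than in WT. Among 49 cytosolic ribosomal protein genes 39 rose and none fell (49 and 0 adjusted over the list alone), with a median of 0.61 (camera adjusted p = 4.53e-16, and adjusted p = 0.386 with an estimated correlation). RPL7 went from 895 to 1526 CPM (0.77 ± 0.12, adjusted p = 0.000773) and RPL11 rose by 0.75 ± 0.12. Of 70 nuclear genes of the respiratory chain 43 rose and none fell (53 and 0 adjusted over the list alone), with a median of 0.49 (adjusted p = 1.5e-14, and adjusted p = 0.386 with an estimated correlation). The ATP synthase subunits ATP5MC1 and ATP5F1C rose by 0.86 ± 0.15 and 0.69 ± 0.11, and COX5A of complex IV by 0.65. Of 13 mitochondrially encoded mRNAs 10 rose (11 adjusted over the list alone), with a median of 0.85 (adjusted p = 4.46e-09, and adjusted p = 0.215 with an estimated correlation), led by MT-ND2 from 220.7 to 597.4 CPM (1.44 ± 0.11, adjusted p = 1.64e-06) and MT-ND3 (1.43 ± 0.12). Reads of mitochondrially encoded genes that also map to close copies were left out, so their levels are uncertain. Transcripts of the ribosomal, respiratory chain and mitochondrial lists are short. With the counts corrected for length the medians of these lists were 0.36, 0.26 and 0.61 (adjusted p = 9.91e-12, 1.36e-07 and 0.000335), with 35 ribosomal and 25 respiratory chain genes called. In the tricarboxylic acid cycle 5 of 25 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.0207, and adjusted p = 0.362 with an estimated correlation). SDHB rose by 0.64 ± 0.13 and MDH2 by 0.55 ± 0.13, while IDH2 and OGDH, chosen after their values were seen, changed by -0.40 (adjusted p = 0.0481) and -0.33 (adjusted p = 0.0395). The call for the cycle was lost with the length correction (adjusted p = 0.105), with library totals alone (0.0527) and with the block genes left out (0.0753).

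Steroidogenesis as a list rose in the libraries labelled OE too, with 9 of 20 genes higher and 1 lower (10 and 1 adjusted over the list alone) and a median of 0.39 (adjusted p = 0.000323, and adjusted p = 0.215 with an estimated correlation). After the length correction the median was 0.39 (adjusted p = 0.000651). Beside HSD3B2 and CYP21A2, SCARB1 rose by 0.83 ± 0.11, and the electron donors FDXR by 0.70 ± 0.16 and POR by 0.53 ± 0.12. H6PD, which supplies NADPH in the endoplasmic reticulum, changed by -0.76, and by -0.33 after the length correction (adjusted p = 0.0949). In cholesterol biosynthesis 9 of 25 rose and none fell (12 and 2 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.00852, and adjusted p = 0.215 with an estimated correlation). Targets of NRF2, the regulator of the oxidative stress response, had 9 rises and 1 fall among 28 (11 and 1 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.00898, and adjusted p = 0.362 with an estimated correlation). NQO1 rose by 0.91 ± 0.13, TXN by 0.87 and FTH1 by 0.74, and SLC7A11, the cystine importer, chosen after its values were seen, changed by -0.66 ± 0.19 (adjusted p = 0.0244). The medians of these lists after the length correction were 0.20 (adjusted p = 0.01) and 0.14 (adjusted p = 0.0116).

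Targets and components of Wnt signalling were lower in the libraries labelled OE than in WT. Of 22, 11 fell and none rose (13 and 0 adjusted over the list alone), with a median of -0.51 (adjusted p = 6.39e-05, and adjusted p = 0.362 with an estimated correlation). Of the members with the smallest p, NOTUM, NKD1 and APCDD1 are known as inhibitors of the pathway. NOTUM, which inactivates Wnt proteins, went from 20.6 to 4.8 CPM (-2.08 ± 0.20, adjusted p = 1.52e-05), NKD1 changed by -1.37 ± 0.19, APCDD1 by -0.73 ± 0.10 and ISM1 by -0.90 ± 0.14. After the length correction the median was -0.46 (adjusted p = 0.00017), NOTUM was at -2.16, and NKD1, with 17105 nt, was at -0.70. In the extracellular matrix list 21 of 38 fell and 1 rose (22 and 4 adjusted over the list alone), with a median of -0.66 (adjusted p = 0.000244, and adjusted p = 0.404 with an estimated correlation). The proteoglycan VCAN changed by -1.97 ± 0.23 and the fibrillin FBN2 by -1.70 ± 0.21, while the integrin ITGB5 rose by 0.94 ± 0.12. Matrix transcripts are long (12625 nt for VCAN), and after the correction VCAN was at -1.41 and the list's median at -0.38 (adjusted p = 0.00674).

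Genes of cAMP signalling through protein kinase A had 6 falls and 2 rises among 24 (10 and 2 adjusted over the list alone), with a median of -0.37 (adjusted p = 0.00238, and adjusted p = 0.386 with an estimated correlation). The anchoring protein AKAP12 changed by -1.50 ± 0.23, the adenylate cyclase ADCY3 by -0.71, and PDE4D, which degrades cAMP, by -0.93 ± 0.16, while the transcription factor CREM rose by 0.41 ± 0.10 and PDE2A, chosen after its values were seen, by 0.31 (adjusted p = 0.0459). CREM was not called without WT replicate 1 (adjusted p = 0.0535) or 3 (0.066), or with library totals alone (0.0554). In the insulin-like growth factor list 9 of 20 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.63 (adjusted p = 0.00852, and adjusted p = 0.362 with an estimated correlation). IGF1R, the receptor, changed by -1.23 ± 0.18, MEG3 by -1.02 ± 0.12 and PEG3 by -2.14 ± 0.37, while MEST, chosen after its values were seen, rose (adjusted p = 0.0405). After the length correction the cAMP median was -0.21 (adjusted p = 0.0327), the growth factor median was -0.21 and no longer called (adjusted p = 0.0926), and IGF1R, with 12235 nt, was at -0.70. Markers of chromaffin and neural cells, of which 7 were tested, had 4 falls (4 adjusted over the list alone) and a median of -1.0 (adjusted p = 0.00238, and adjusted p = 0.215 with an estimated correlation). CHGB changed by -1.39 ± 0.16, NEFL by -1.16 ± 0.14 and NEFM by -1.0, and the corrected median was -0.89 (adjusted p = 0.000615). In KO 4 of these markers fell and 2 rose (median -0.77, adjusted p = 0.232), with CHGB at -1.27, NEFL at -1.12 and SYP at -1.02 against GAP43 at 1.52. SREBF1 was lower in the libraries labelled OE as well (-1.41 ± 0.19), as was the fatty acid synthase FASN (-1.04 ± 0.20, and -0.63 after correction).

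Sphingolipid genes did not move as a group in the libraries labelled OE either, with 5 rises and 1 fall among 38 (median 0.04, adjusted p = 0.432). SPHK1, the kinase that makes S1P, went from 0.96 to 3.14 CPM (1.69 ± 0.51, adjusted p = 0.0266) and the ceramide synthase CERS5 rose by 0.53 ± 0.14 (adjusted p = 0.0145). SPHK1 was not called without WT replicate 2 (adjusted p = 0.0696), WT replicate 3 (0.104), OE-labelled replicate 2 (0.0523) or OE-labelled replicate 3 (0.148), and CERS5 not without WT replicate 1 (0.0846) or 3 (0.0671). Of 7 receptors and transporters of S1P none rose and 2 fell (3 and 2 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.752). The 2 were the exporters ABCC1 (-0.87 ± 0.18, adjusted p = 0.00392, and -0.56 after the length correction) and ABCA1 (-1.12 ± 0.32, adjusted p = 0.02). ABCA1 was not called after the correction (0.124), nor without WT replicate 3 (0.132), OE-labelled replicate 1 (0.0703) or OE-labelled replicate 2 (0.0641). The receptor S1PR3 was at 0.34 ± 0.15 (adjusted p = 0.111), and at 0.72 after the correction (adjusted p = 2.34e-05), and the corrected list held 1 rise and 1 fall (median 0.28, adjusted p = 0.516).

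**Figure D4:**
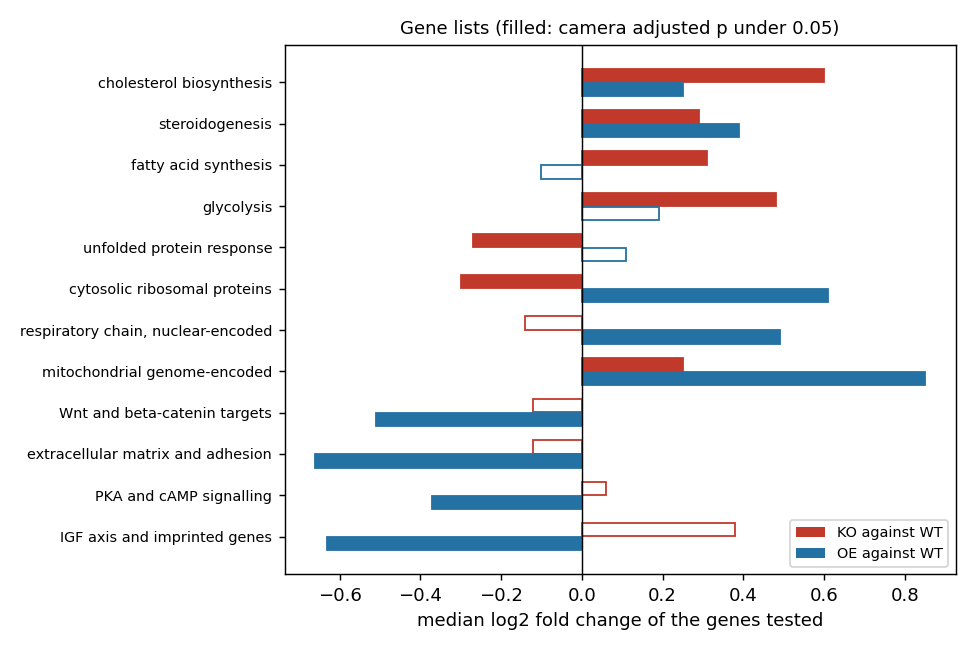
Median log2 fold change of 12 gene lists for KO against WT (red) and OE against WT (blue). Filled bars have a camera adjusted p under 0.05 with the preset correlation. Cholesterol biosynthesis has medians of 0.60 and 0.25, steroidogenesis of 0.29 and 0.39, and ribosomal proteins of -0.30 and 0.61.

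The libraries labelled OE and KO, whose SGPL1 levels differed by 0.95 ± 0.14 on the log2 scale (adjusted p = 6.7e-05), differed in more genes than either did from WT. RAB31 was at least 61.7-fold higher in the libraries labelled OE, CYP27A1 had a ratio of 453 (125 to 3750), and EYA2 and GALNT12 were higher by 5.23 and 5.09 on the log2 scale. CILP2 was at -7.75 ± 0.33, NAXD at -6.54, and KCNT2 was higher in KO with a ratio of 150 (41.3 to 1250). A total of 2692 genes were higher and 2920 lower (39.7% of those tested), with 1923 at least 2-fold changed, and the groups did not overlap in 7319 genes (51.7%, where chance gives 10%). Ribosomal proteins had 49 of 49 members higher and a median of 0.95 (adjusted p = 8.24e-17, and adjusted p = 0.484 with an estimated correlation), and the respiratory chain 57 of 70 higher and 1 lower with a median of 0.63 (adjusted p = 1.45e-11, and adjusted p = 0.547 with an estimated correlation). Mitochondrially encoded mRNAs had 8 rises and a median of 0.63 (adjusted p = 0.00149, and adjusted p = 0.484 with an estimated correlation). The unfolded protein response had 11 rises and 2 falls (median 0.29), with HSPA5 at 0.95 and SDF2L1, a cofactor of that chaperone, at 1.83 ± 0.18. Fatty acid synthesis had 11 falls and no rise (median -0.53, adjusted p = 0.00274), and cholesterol biosynthesis 14 falls and 3 rises (median -0.36), with SQLE at 1.35 and PMVK at 1.29 against the list. These 3 lists had an adjusted p of 0.418 with an estimated correlation, and the unfolded protein response and cholesterol biosynthesis an adjusted p of 0.0162 with the preset one. After the length correction the medians were 0.51 for ribosomal proteins (48 higher, adjusted p = 2.6e-14), 0.26 for the respiratory chain (37 higher and 1 lower, adjusted p = 6.98e-05) and -0.32 for fatty acid synthesis (adjusted p = 0.00767). With an estimated correlation these had adjusted p = 0.39, 0.48 and 0.176. HSD3B2 was higher by 2.02, while SULT2A1 was at -1.20 and SOAT1 at -1.63.

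Lower in the libraries labelled OE than in KO were also the insulin-like growth factor list (13 falls, 3 rises, median -0.93, adjusted p = 0.0162), Wnt signalling (10 and 3, -0.31, 0.0162), cAMP signalling (10 and 1, -0.43, 0.0206) and hypoxia targets (10 and 2, -0.33, 0.0245). The list of S phase genes had 11 falls and 2 rises (-0.14, 0.0319), histones 5 and 0 (-0.23, 0.0332) and G2 and M phase 16 and 5 (-0.26, 0.0467). Examples were IGF1R at -1.45, the stem cell marker LGR5 at -1.92, AKAP12 at -2.08, EGLN1 at -1.41, the histone H1-2 at -1.22, FOXM1 at -1.18 and CENPF at -1.99. With an estimated correlation these lists had adjusted p = 0.484 for growth factors, hypoxia, histones and both cell cycle lists, 0.502 for Wnt and 0.547 for cAMP. The median fell with length from 0.4 in the shortest to -0.451 in the longest genes, and after the length correction the mitochondrial (adjusted p = 0.306), growth factor (0.0613), cAMP (0.154) and hypoxia (0.0739) lists were not called. Histones were then at -0.74 with 8 lower (6.98e-05), S phase at -0.17 (0.00744) and G2 and M phase at -0.27 (0.00171), with adjusted p = 0.101, 0.39 and 0.39 with an estimated correlation. Because the libraries were poly-A selected, the counts of these replication-dependent histones may not follow their expression. Left-out libraries ended the call for cAMP (OE-labelled replicate 2, 0.0598) and hypoxia (KO replicate 2, 0.0651). For S phase they were WT replicate 2 (0.0539), KO replicate 1 (0.0645) and OE-labelled replicate 1 (0.093). For histones they were WT replicates 1 (0.0899), 2 (0.0852) and 3 (0.0854), KO replicates 1 (0.135) and 2 (0.112), and OE-labelled replicates 1 (0.215) and 3 (0.0629). For G2 and M phase they were WT replicates 1 (0.0627), 2 (0.0549) and 3 (0.0587), KO replicate 3 (0.0693), and OE-labelled replicates 1 (0.093), 2 (0.0509) and 3 (0.0595). Histones also lost the call with DESeq2 (0.273), without a filter (0.237) and with only the 2 groups compared in the fit (0.0585). S phase and G2 and M phase lost it with upper-quartile scaling (0.0665 each) and with only the 2 groups compared (0.0585 and 0.0629), and cAMP with WT replicate 2 and OE-labelled replicate 2 left out together (0.0591).

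Genes that moved in both KO and the libraries labelled OE, each against the same WT libraries, numbered 417 in the same direction and 216 in opposite directions. Of the 417, 166 were higher and 251 lower in both, where independent lists would share 125 and 150. Of the 216, 101 were higher in KO and lower in the libraries labelled OE and 115 the reverse, where independent lists would share 143 and 131. Unchanged groups simulated against the same WT libraries gave 0 of either. They were drawn around the mean of these WT libraries, so overlap or correlation from error in that mean could not appear. The simulated values are thus no measure of the effect of shared controls. With 3 WT libraries the controls could not be split into parts of at least 2, so part of the excess may come from the shared controls. The log2 fold changes had a correlation of 0.165 across genes (simulated 0.006) and a covariance of 0.08 (simulated 0), and genes are not independent replicates. Shared rises included SCARB1 and LDHA (0.62 ± 0.11 in both), and shared falls SREBF1, VCAN (-2.07 ± 0.24 in KO) and APCDD1 (-0.69 ± 0.10 in KO). Opposite were ITPR1, a calcium channel of the endoplasmic reticulum (1.62 ± 0.20 and -1.60 ± 0.22), and FXYD6, a regulator of the sodium pump (1.66 ± 0.21 and -1.18 ± 0.25). IGF2 (chromosome 11, 2129112 to 2141238), a growth factor often raised in adrenocortical carcinoma, was at 55.2 ± 32.5 CPM in WT, 146 ± 38.7 in KO and 20.3 ± 11.3 in the libraries labelled OE (1.40 ± 0.38, adjusted p = 0.0162, and -1.44 ± 0.40, adjusted p = 0.0189). Its KO call was lost without KO replicate 2 (0.0823) and with DESeq2 (0.105), and its OE call without WT replicate 1 (0.0728) or 3 (0.113), without OE-labelled replicate 2 (0.0641) or 3 (0.0643), and with DESeq2 (0.0735). The number of opposite genes was 66 without WT replicate 1, 102 without WT replicate 3, 104 without KO replicate 2 and 128 without KO replicate 3. The number moving the same way was 180 without WT replicate 1, 189 without WT replicate 3, 257 without KO replicate 2 and 274 without OE-labelled replicate 3.

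The other lists were not called. For KO against WT the median was 0.01 for fatty acid oxidation (adjusted p = 0.543), 0.09 for the tricarboxylic acid cycle (0.543), -0.14 for the respiratory chain (0.251), 0.07 for mitochondrial dynamics (0.567), 0.19 for NRF2 targets (0.109) and -0.29 for the integrated stress response (0.306). It was 0.06 for S phase (0.399), 0.04 for G2 and M phase (0.566), 0.2 for histones (0.0771), -0.12 for Wnt targets (0.431), 0.38 for insulin-like growth factors (0.306), 0.06 for cAMP signalling (0.796), 0.15 for hypoxia (0.0647) and -0.12 for the extracellular matrix (0.313). Targets of p53 had a median of 0.01 (0.875), YAP targets 0.2 (0.306), immediate early genes -0.11 (0.431), NF-kB targets -0.13 (0.901), interferon genes 0.15 (0.0647), antigen presentation 0.14 (0.467), the epithelial-mesenchymal transition -0.05 (0.942) and lysosomes -0.01 (0.968). Growth factor, p53, G2 and M phase and cAMP genes had means of -0.05, -0.05, -0.01 and -0.06, opposite in sign to their medians. Some lists passed when 1 library was left out. Without WT replicate 1 these were hypoxia, the integrated stress response and adrenocortical regulators (0.034 each). Without WT replicate 2 they were NRF2, interferon, hypoxia and the extracellular matrix (0.048 each) and histones (0.045), and without WT replicate 3 the respiratory chain (0.0167). Hypoxia also passed without KO replicate 1 (0.0422) and OE-labelled replicates 2 (0.0494) and 3 (0.0482), histones without KO replicate 3 (0.0401) and interferon without OE-labelled replicate 2 (0.0494). With the length correction NRF2 and interferon (0.0474 each) and histones (0.0167) passed. With an estimated correlation these 3 had adjusted p = 0.461, 0.233 and 0.209. Without a filter NRF2 (0.0343), interferon and hypoxia (0.023 each), histones (0.0277) and phosphatidylethanolamine synthesis (0.0343) did. With limma-voom hypoxia, adrenocortical regulators and phosphatidylethanolamine synthesis passed (0.0391 each), with DESeq2 interferon (0.0408), and with only the 2 groups compared phosphatidylethanolamine synthesis (0.0386). With WT replicate 2 and OE-labelled replicate 2 left out together, phosphatidylethanolamine synthesis (0.0232), NRF2 (0.0384), histones (0.0378), interferon and hypoxia (0.0466 each) passed.

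For the libraries labelled OE against WT the median was 0.21 for phosphatidylethanolamine synthesis (adjusted p = 0.117), -0.04 for adrenocortical regulators (0.305, with a mean of 0.08), -0.09 for cholesterol efflux and storage (0.536), -0.1 for fatty acid synthesis (0.0934), 0.15 for fatty acid oxidation (0.305), 0.19 for glycolysis (0.0997) and 0.14 for mitochondrial dynamics (0.329). It was 0.11 for the unfolded protein response (0.146), -0.25 for the integrated stress response (0.117), -0.09 for S phase (0.0682), -0.1 for G2 and M phase (0.0519), -0.1 for histones (0.385) and -0.16 for hypoxia (0.385). Targets of p53 had a median of 0.01 (0.972, with a mean of -0.05), YAP targets -0.24 (0.385), immediate early genes 0 (0.713), NF-kB targets -0.01 (0.993), interferon genes 0.16 (0.262), antigen presentation 0.18 (0.385), the epithelial-mesenchymal transition -0.11 (0.174) and lysosomes -0.04 (0.993, with the test pointing up). S phase passed without WT replicate 3 (0.0251) or OE-labelled replicate 2 (0.0316), G2 and M phase without WT replicate 1 (0.0282) or 3 (0.0216), and the integrated stress response without WT replicate 1 (0.00494) or OE-labelled replicate 2 (0.0253). S phase and G2 and M phase also passed with library totals alone (0.00993 and 0.0188) and with limma-voom (0.0371 and 0.019). Fatty acid synthesis and glycolysis passed with limma-voom (0.0371 and 0.0475) and without a filter (0.0481 each), as did phosphatidylethanolamine synthesis (0.0446), the unfolded protein response (0.0481) and the epithelial-mesenchymal transition (0.0416) without a filter. After the length correction 8 more lists were called, namely G2 and M phase at -0.20 (0.000422), S phase at -0.12 (0.01), histones at -0.42 (0.00556), the integrated stress response at -0.24 (0.0464), phosphatidylethanolamine synthesis at 0.25 (0.034), glycolysis at 0.14 (0.036), the unfolded protein response at 0.12 (0.036) and adrenocortical regulators at 0.18 (0.0421), whose median was negative before. None of the lists called for OE against WT after this correction was called with an estimated correlation (adjusted p = 0.161 to 0.532).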

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

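Chosen after the results were seen were the transcript length correction, leaving out WT replicate 2 and OE-labelled replicate 2 together, and leaving out the genes of the chromosome blocks, which then have no value. Over all settings except those leaving out 1 library, these 3 included, 200 of 221 counts and SGPL1 values stayed within 1.5 times or on the same side of the threshold. Among named genes 6510 values stayed on the same side, 113 lost and 77 gained a call and 1 reversed, and among lists 1356 stayed, 55 lost and 59 gained a call. RLE scaling and the filter of 1 CPM in 3 libraries moved no count by over 1.5 times. With library totals alone 765 genes were higher in the libraries labelled OE than in WT, because the median of all genes moved to -0.129. Without a filter 12 lists were called for KO against WT and 359 genes moved in opposite directions. At an adjusted p under 0.01, a stricter threshold by construction, 713 genes were higher and 712 lower in KO, 454 higher and 699 lower in the libraries labelled OE with 432 at least 2-fold changed, 1705 were higher in the libraries labelled OE than in KO, 46 moved in opposite directions and 131 in the same direction. Camera with an estimated correlation called 1 list for KO against WT, 0 for OE against WT and 0 for OE against KO (4, 4 and 3 at an unadjusted p under 0.05), against 7, 12 and 13 with the preset correlation. Fry, which does not compare a list with other genes, called 12, 18 and 22. With the transcript length correction 668 genes moved in the same direction, and SELENOI, OE against KO, went from -0.45 to 0.05 (adjusted p = 0.719). This correction shared 97.9% of the KO calls, 69.7% of the OE calls and 71.3% of the OE against KO calls. Without WT replicate 2 and OE-labelled replicate 2 there were 11 lists for KO against WT and 716 genes in the same direction. With the block genes left out 142 genes moved in opposite directions. Apart from the smaller number of genes, the other threshold and the scaling shift, the cause was not tested.

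Leaving out 1 library at a time gave 879 to 1570 genes higher and 885 to 1644 lower in KO than in WT, both lowest without KO replicate 2, with 891 to 1144 at least 2-fold changed and 4 (without KO replicate 2) to 11 lists (without WT replicate 2). For OE against WT it gave 485 to 1798 higher and 759 to 1875 lower, 385 to 949 at least 2-fold changed and 12 to 14 lists, in each count of genes lowest without WT replicate 3 and highest without WT replicate 2. Of the OE calls 41.9% were shared without WT replicate 3 and 46.5% without WT replicate 1. For OE against KO it gave 2063 to 2921 higher, 2307 to 2982 lower, 1601 to 2208 at least 2-fold changed and 10 to 12 lists. Genes moving in opposite directions numbered 66 (without WT replicate 1) to 219 and in the same direction 180 (without WT replicate 1) to 523 (without WT replicate 2). SGPL1 stayed at -1.05 to -0.90 for KO against WT, -0.08 to 0.09 for OE against WT and 0.89 to 1.07 for OE against KO. Among named genes 330 of these values lost and 30 gained a call, and among lists 31 and 22. Fewer libraries lower the power to call a gene, but some left-out libraries raised the number of calls. Without WT replicate 2, 1798 genes were higher and 1875 lower for OE against WT, against 1365 and 1559 with all libraries. Without OE-labelled replicate 2, 1570 were higher and 1644 lower for KO against WT, against 1296 and 1359. The cause of these shifts was not tested. With about 8006873 to 10895080 counts per library, a gene at the floor of 3 counts lies near 0.35 CPM. The filter of the main fit, with a minimum count of 10, set a higher limit. Genes that did not reach about that count in enough libraries were not tested, so their changes were not detectable.

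With the replicate number as a block, 1622 genes were higher and 1613 lower in KO than in WT, 1820 and 1937 in the libraries labelled OE than in WT, 2929 and 3206 in the libraries labelled OE than in KO, and 463 moved in opposite directions. The mitochondrially encoded and unfolded protein lists for KO against WT (adjusted p = 0.0555 each) and G2 and M phase for OE against KO (0.05) were then not called. The labels do not say that a number marks a shared day or culture. The deviations of same-numbered libraries had correlations of 0.06, -0.035 and 0.172 between WT and KO, 0.013, 0.246 and 0.136 between WT and OE, and -0.138, -0.007 and 0.134 between KO and OE, and 5 of 9 libraries were closest to their own number, so the numbers were not taken to pair the libraries.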

Other observations

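Chosen only after the results were seen were the tests of SGPL1 mRNA as a source of the OE differences and of cells of another line, and the transcript length correction. Some single genes not yet described differed between KO and WT, in lists that were not called for this comparison (extracellular matrix, adjusted p = 0.313, lysosomes, 0.968, integrated stress response, 0.306). The membrane protease MMP14, which activates other matrix proteases, changed by -1.84 ± 0.17 in KO and MMP2 by -3.56, the hyaluronan receptor CD44 was at least 8.83-fold lower, and the cathepsins CTSB and CTSL changed by -1.36 ± 0.11 and -0.61. PPP1R15A, which restores translation after stress, changed by -1.0 ± 0.16 and ATF4 by -0.74 ± 0.16 in KO, and ATF4 by -1.10 ± 0.16 in the libraries labelled OE. The binding protein IGFBP3 changed by -2.62 ± 0.26 in KO and by -1.16 in the libraries labelled OE.

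SGPL1 counts were not higher in the libraries labelled OE than in WT, where genes as long and as expressed had a median of -0.21 and SGPL1 lay at percentile 71.2 of the 500 nearest. A place inside the central 95% of these genes was set in advance to exclude a rise hidden by the length trend, but they spread from -1.06 to 0.48, so a moderate rise would lie inside it too. With the corrected change at 0.23 (95% interval -0.03 to 0.50) a hidden rise of that size stays open. All 6 libraries had a higher mean correlation with their own label, so 0 were out of place, which argues against single libraries swapped between OE and WT. Single pairs separated less clearly. WT replicate 2 was at 0.9748 with OE-labelled replicate 3 and 0.9745 with WT replicate 3. OE-labelled replicate 1 was at 0.9743 with WT replicate 2 and 0.9731 with OE-labelled replicate 2. A vector-borne sequence that does not map to the gene, and overexpression lost from the culture, were not tested.

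Ribosomal protein and respiratory chain genes were higher in the libraries labelled OE than in WT. Their medians of 0.61 and 0.49 were set beside 10000 lists matched on length and expression, with medians of 0.39 (0.29 to 0.49) and 0.35 (0.25 to 0.43). The lower of the 2 percentiles was 99.98. The length trend may thus account for part of the shift, and with the lengths used here it left an excess. Each gene had the length of a single annotated transcript (3437 nt for RPS23 and 5484 nt for ATP5MC3, against list medians of 1041 and 1080 nt). A length too long for a member matches it to genes that are too long, so length as the whole source is not excluded. The drawn genes also need not move together as list members may. Matching on expression was imperfect for ribosomal genes (a median of 813 against 454 CPM). Over the 3 other scalings the lowest median of the 2 lists was 0.37, so the medians stayed positive under each. Scaling moves all genes of a library alike, so the place of the lists among the other genes could hardly change. That both lists kept their call under these scalings is therefore no evidence. Whether higher SGPL1 mRNA drives the shift stays open, since the upper 95% bound of its change was 0.5 with the length correction.

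Blocks of neighbouring genes were shifted in KO, with the largest median over 51 genes at 1.09 in size on chromosome 5 from 172958729 to 178630615 (95th percentile of 1000 random gene orders 0.33), in line with a copy-number difference between the lines as a hypothesis. For OE against WT the largest was 0.34, under the 95th percentile of 0.38. A total of 10 called genes had at most 3 counts over the libraries of KO or WT and at least 5 CPM in the other. Their neighbours had a median signed change of 0.12 (95% interval 0.01 to 0.30). For these genes as a set this argues against loss or gain of segments that span most of the 20 neighbours of a gene. The neighbours of MARVELD2 and TDO2 were nevertheless at 0.56 and 0.44. A shorter loss or gain would not move these medians and stays open. Cells of another line in the cultures stay open, as the steroidogenesis median of 0.29 does not bear on a line that also makes steroids. The 20 neighbours of SGPL1, from 69801867 to 72355149, had a median of -0.01 (-0.30 to 0.35), and 4 of them were called. This argues against loss of a segment that spans most of these neighbours as the source of the lower SGPL1 counts. A loss of SGPL1 alone or with a few neighbours would not move this median and stays open. A biological difference by genotype stays untested beside clonal differences.

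Other splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. For the gene counts 1 of 10 splits, the labelled one, was as large, and the highest other gave 0 genes, against 1296 higher and 1359 lower with 1046 at least 2-fold changed in KO, 1365, 1559 and 664 for OE against WT, and 2692, 2920 and 1923 for OE against KO. For lists, 2 of 10 splits gave at least the 7 called for KO against WT, the highest other being 12 with WT replicates 1 and 3 and KO replicate 3 on one side. The highest other was 8 lists against 12 for OE against WT and 8 against 13 for OE against KO. Of 100 groupings of the 9 libraries, 1 gave as many as the 216 genes in opposite directions (highest other 25), and 3 gave as many as the 417 in the same direction, shares under 0.05 in both cases. The highest other, 1903, kept the groups intact with KO as the reference. The next, 1318, had KO as the reference with WT and OE mixed. Both point to the distance of KO from the other libraries. Most groupings mix libraries that differ, which widens the spread within groups and leaves few calls whatever their directions. The shares therefore cannot tell whether the overlaps arose by chance.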
